A study of Mus musculus with 12 samples.

How the data were processed

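RNA was measured in 12 libraries of mouse haematopoietic stem and progenitor cells, 6 naive and 6 recovered from the brain, and each library was placed in its group by its title. Per the labels' protocols, cDNA was made and amplified directly from lysate with a low-input template-switching kit (SMARTer Ultra Low Input v3), cut and tagged with Nextera XT, and sequenced on an Illumina HiSeq. Such amplification starts from little RNA, so single molecules can be lost or amplified unevenly between libraries. Per the submitters' processing notes, Trimmomatic 0.32 and the genome build GRCm38 were used. The aligner, the counting tool and the annotation release are not given in the sources used here. The labels do not say whether the replicates of a group are separate animals or cell preparations, so p-values measure the spread between these samples, which may be technical.

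The authors deposited a single table with 1 value per entry and library, a fold change and a P, and its header names no unit. The deposited values were treated as RPKM, reads per length of gene model and per a library factor, because within an entry every value above 0 is a whole number of reads divided by 1 length and multiplied by 1 constant per library. Such whole reads were found for 24385 of the 24388 entries above 0 (tolerance 0.004 of a read plus a small part in proportion to the reads). The remaining 14536 of 38924 entries were 0 in all libraries. The library constant is not the total of the reads. The design fixed before the data were examined named a count test first, and limma on log2(value + 1) should the table hold normalized values. The table held another unit than counts, so limma was used. The authors' deposited fold change is the ratio of the group means, and their deposited P equals an equal-variance test on the untransformed values in 24388 of 24388 entries within 1e-06. The precision of a value is set by the reads behind it, 638594 to 13337354 per library. PCR reads without molecular identifiers are not independent molecules. Genes used by every cell are also listed at 0 in some libraries, so a 0 is given as listed and values are given per library.

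The entries carry Ensembl gene identifiers, and 37607 of 38924 were matched to gene names in GENCODE release M21 on GRCm38, which also gave the coordinates. Because the length behind each entry can be recovered from its values, it was set against the exon length of the labelled gene. Of 22546 entries with enough values and an annotated length, 10626 (47.1%) had the length of the labelled gene and are called entries of exact length below. A length that went into that of the gene a small whole number of times also counted as a match. Of 88 runs of at least 10 consecutive mismatches, 40 were set aside. A run was set aside where at least 2 of its entries had the lengths of genes at a shared offset, up to 400 places away alphabetically. Any run of at least 25 mismatches was set aside as well. Labels in these 40 runs were not used. Unless their own length matched, neither were those of the 2735 entries whose alphabetical rank depends on how hyphens are sorted. The same held for entries with the length of another gene within 40 places and entries over 2 times longer than the labelled gene. This left 2876 entries above 0 without a name, and 10886 kept the deposited label only because none of these rules excluded it. No match of a neighbouring entry was required for that. This check was designed after the data were seen and was revised several times on seeing labels it kept or dropped. Entries without a name stayed in the test over all entries. No gene was named from its place in the table. Of the 17 genes named by the rule below that passed the threshold, 10 are entries of exact length (Actb, Rpl23, Cst3, Srgn, Serinc3, Tmsb4x, Tuba1b, Mpo, Ier2 and Hsp90b1). The other 7 kept their label because no rule excluded it.

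Differences between groups were tested with limma 3.58.1 in R 4.3.3 (eBayes with a trend, 2 groups, no covariates) on log2(value + 1), over entries with a value of at least 1 in at least 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. No normalization between libraries was added to the authors' own. In this fit the weight given to the variance trend was infinite. Each limma SE and p therefore rested on the spread pooled over entries of like abundance, and not on the entry's own spread. Of 32 gene lists chosen from textbook knowledge before the data were examined, with 471 genes of which 435 had a usable label, 31 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, with the correlation estimated as an alternative. Sums of values over 16 lists of cell type markers were compared by exact two-sided permutation tests of the mean log2(sum + 1), over all 924 assignments of 12 libraries, adjusted over the 16 lists. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No 2 libraries were near-identical, since no pair had r above 0.253.

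The text names the entries labelled Mt1 and Mt2, up to 10 genes per direction with the largest change among those past the threshold with a mean of at least 10 in the higher group, leaving out predicted genes and receptor segments, up to 4 genes with the smallest p from each list, and abundant members of cell type lists. From the genes this rule yields, those printed were picked after their values were seen, and all 17 that passed the threshold are among them. Some genes that the rule or a count covers are not reported here. The rule asked for no overlap between the groups unless fewer than 5 genes met that, which was the case, so it was dropped. Tests were tried on simulated data built on the 17689 tested entries of this comparison. The values of each entry were first shuffled between libraries, independently of other entries. That removed the differences between sparse and other libraries, so the results do not describe performance under that structure. With 50 entries raised and 50 lowered at each size, a change of 4 on the log2 scale was found in 13 raised and 10 lowered entries and a change of 8 in 48 and 50, with 13 calls among entries not moved, a share of all calls above the 0.05 allowed. Reads of ribosomal protein genes, Actb, Tmsb4x and other genes with processed pseudogenes or near-identical relatives may have been divided among copies, and their values are uncertain to that extent.

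The alternatives were quantile normalization, library totals and upper quartile scaling, sample quality weights, no filter, a filter of at least 10 in 6 libraries and a pseudocount of 0.1. Further ones were a 2-fold minimum, a test against a 1.5-fold change, the label numbers 1 to 6 or 7 to 12 as a term, and each library left out in turn. For lists fry was added, and for sums the median of log2 values and the sum without the most abundant member. Alternatives that need counts were not run because the deposited values are not counts. Reads recovered from the values were used for library totals and shares of reads, but no count test was run on them. For lists, the alternatives are given for the 5 that passed and for zinc handling. Comparisons of 3 against 3 libraries cannot give an exact permutation p below 0.1. Chosen after seeing the data were the omission of the libraries with fewer than 10000 entries above 0, libraries 1 to 6 and 7 to 12 alone, a variance prior without a trend, lists on entries of exact length only, and lists on all labels as deposited. The labels state no batch, and the number ranges were tried only as a possible one.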

Results

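Transcripts were measured by RNA sequencing in mouse haematopoietic stem and progenitor cells, the blood-forming cells of the bone marrow. The cells came from male C57BL/6 donors and were enriched by removing marrow cells that carried CD45R, CD11b, CD3e, Ly-6G or TER119, surface proteins of maturing blood lineages. In the naive group, 6 libraries (replicates 1, 2, 3, 7, 8 and 9) were made from cells that were not injected. In the brain-recovered group, 6 libraries (replicates 4, 5, 6, 10, 11 and 12) were made from injected cells. These were given into a vein 24 h after cerebral ischaemia and reperfusion, the loss and return of blood flow that models stroke, and were taken out of the brain 24 h after the injection. The comparison of the 2 groups asks how transcript levels in cells that had reached the injured brain differed from those in cells that had not been injected. The title of the series points to metallothionein I, a small metal-binding protein.

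The number of reads behind the deposited values, recovered from the steps between them, ran from 638594 to 2293126 in the naive libraries and from 1033759 to 13337354 in the brain-recovered libraries. The mean log2 number of reads was higher by 1.76 in the brain-recovered group (exact permutation p = 0.0173, two-sided, n = 6 per group). Of the 38924 entries of the table, those above 0 numbered 7164, 5818, 5067, 18753, 16269 and 23184 in naive replicates 1, 2, 3, 7, 8 and 9. They numbered 19489, 22727, 16237, 12066, 21482 and 4380 in brain-recovered replicates 4, 5, 6, 10, 11 and 12 (exact permutation p = 0.435 for the difference of means, n = 6 per group). The median value above 0 lay between 10.8 and 12.6 in all 12 libraries. The 99th percentile of values above 0 ran from 36.4 to 415 in the naive group and from 246 to 11652 in the brain-recovered group. The mean value of olfactory receptor genes was 0.0717 to 0.431 times that of other protein-coding genes, leaving out vomeronasal receptor and mitochondrially encoded genes, in the naive libraries and 0.01995 to 0.170 times in the brain-recovered libraries (exact permutation p = 0.0238, n = 6 per group). With the most abundant 1% of the entries above 0 left out of both means in each library, it was 0.730 to 1.46 and 0.0858 to 1.21 times (exact permutation p = 0.190). Pearson's r between log2 values of 2 libraries, taken across genes, ran from 0.0358 to 0.253 over the 66 pairs. It had a median of 0.0817 within the naive group, 0.142 within the brain-recovered group and 0.0843 between the groups. The first principal component took 36.2% of the variance. It placed naive replicates 1, 2 and 3 and brain-recovered replicate 12, the 4 libraries with fewer than 10000 entries above 0, at 184 to 251. The other 8 libraries lay between -165 and -10.9.

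Brain-recovered cells had higher values of Actb, Rpl23 and Cst3, among other abundant transcripts. Actb encodes cytoplasmic beta-actin (ENSMUSG00000029580, chromosome 5, 142903115 to 142906754 in GRCm38). Its values were 6.67 to 128 in the naive libraries, 1518 to 39162 in brain-recovered replicates 4, 5, 6, 10 and 11, and 61.4 in replicate 12. This was a log2 difference of 7.26 ± 1.49 (SE, n = 6 per group, limma adjusted p = 0.00198). Rpl23, a gene of the large ribosomal subunit (ENSMUSG00000071415, chromosome 11, 97777527 to 97782437), had the largest log2 difference among the named genes, 7.96 ± 1.41 (SE, limma adjusted p = 0.000137). Its values were 0 to 11.6 in the naive libraries and 83.2 to 14403 in 5 of the 6 brain-recovered libraries, with 0.447 in replicate 12. Cst3, which encodes the protease inhibitor cystatin C (ENSMUSG00000027447, chromosome 2, 148871722 to 148875692), rose by 7.31 ± 1.42 on the log2 scale (SE, n = 6 per group, limma adjusted p = 0.000702). Its values were 0.563 to 16.2 in the naive libraries, 346 to 19089 in replicates 4, 5, 6 and 10, 14.7 in replicate 11 and 1.25 in replicate 12.

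In the test over all 17689 entries that passed the filter, 65 were higher and 0 were lower in brain-recovered cells (limma, adjusted p below 0.05), against 1075 higher and 31 lower at an unadjusted p below 0.05. The 65 differences ran from 4.90 to 8.10 on the log2(value + 1) scale, which understates the change of low genes, and their median was 5.95, beside a median of 0.64 over all entries tested. Of the 65 entries, 47 kept a gene name and 18 did not. Other genes with large differences were Rpl8, also of the large ribosomal subunit (7.93 ± 1.43, SE), Myl6, a myosin light chain (7.28 ± 1.39), and Serinc3, a membrane protein of the serine incorporator family (6.61 ± 1.43). Tmsb4x, which encodes the actin-binding peptide thymosin beta 4, and Tuba1b, an alpha-tubulin, had differences of 6.61 ± 1.49 and 6.53 ± 1.41. The limma adjusted p of these 5 genes lay between 0.000164 and 0.00559. Tmsb4x stood at 3261 in naive replicate 1 and between 1.44 and 21.4 in the other naive libraries. Brain-recovered replicates 4, 5, 6, 10 and 11 had 964 to 46120 and replicate 12 had 2.31. Rpl8 reached 172 to 11504 in those 5 brain-recovered libraries, 2.75 in replicate 12 and 51.5 in naive replicate 3, and lay at or below 1.55 in the other 5 naive libraries. In 3 of the called genes no naive library overlapped a brain-recovered one. Over all 17689 entries tested, 26 had no overlap in the higher and 4 in the lower direction, where chance, at 0.216% of entries, gives 38.3. Among them, picked out after their values were seen, were Rps10 of the small ribosomal subunit (6.00 ± 1.33) and Ybx1, which encodes an RNA-binding protein (5.24 ± 1.32). The Ybx1 call was lost without naive replicate 1, 2, 3 or 7 (limma adjusted p 0.102, 0.0775, 0.0689 and 0.133) without brain-recovered replicate 4 or 5 (0.104 and 0.205), with upper quartile scaling (0.0515) and against a 1.5-fold change (0.0698). The Tmsb4x call was lost without naive replicate 8 (0.0616) or 9 (0.0703), with a filter of at least 10 in 6 libraries (0.0698) and in libraries 1 to 6 alone (0.157). In 45 of the 65 entries at least 5 brain-recovered libraries exceeded every naive library, and in 55 brain-recovered replicate 12 lay at or below the highest naive value.

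**Figure D1:**
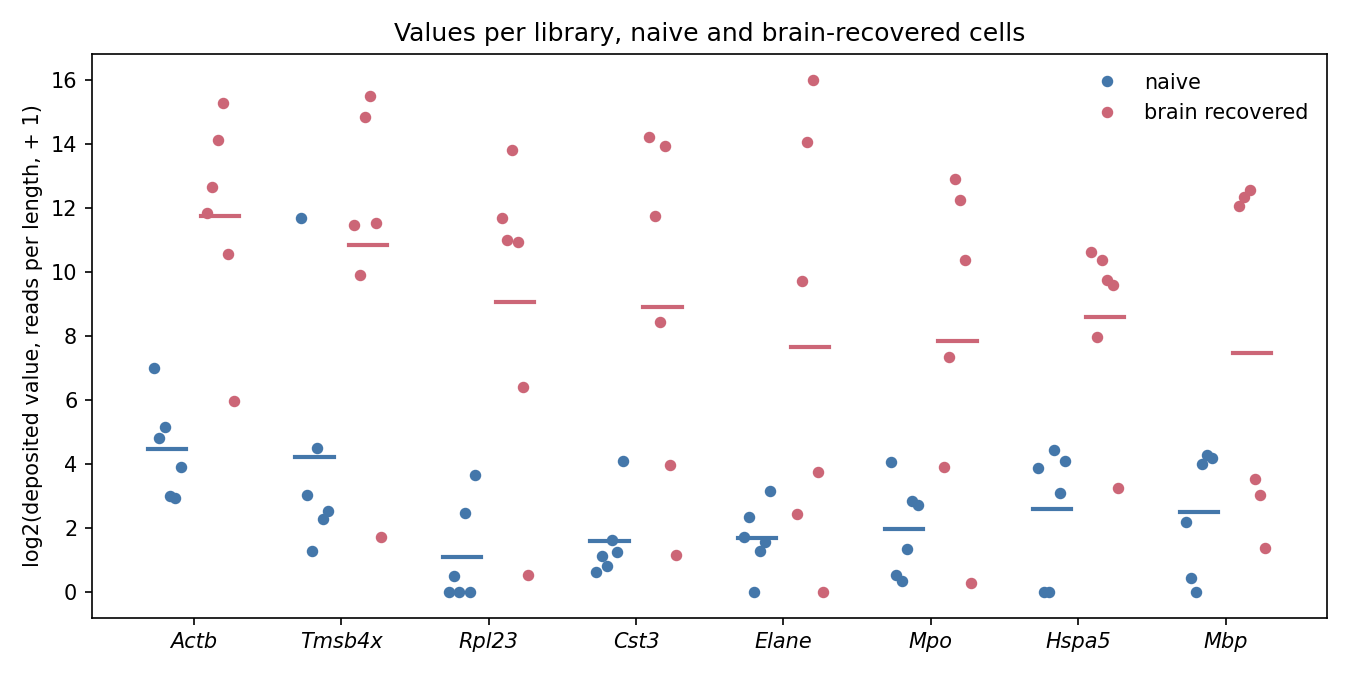
Deposited values of 8 genes on the log2(value + 1) scale, with a point for each library, a line at each group mean, and naive libraries (n = 6) beside brain-recovered libraries (n = 6). For Actb, the brain-recovered libraries other than replicate 12 lie between 1518 and 39162 before the log, above the highest naive value of 128, and Tmsb4x is at 3261 in naive replicate 1.

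The count of called entries depended on scaling and on which libraries entered. It was 0 with limma after quantile normalization, where unadjusted p below 0.05 gave 557 higher and 497 lower and the median over all entries moved from 0.64 to -0.06. It was also 0 after scaling to library totals, where unadjusted p below 0.05 gave 163 higher and 456 lower around a median of -0.49. Every called entry that could be tested kept a higher value in brain-recovered cells in both (65 of 65 and 63 of 63), with median differences of 4.20 and 3.95. That direction is no independent check, because the entries had been selected for large differences in these same libraries. Without the 4 libraries that had fewer than 10000 entries above 0, 3 entries passed (Rpl8, Actb and 1 without a name), and the median difference of the 65 was 6.54. Over all entries tested, unadjusted p below 0.05 then gave 481 higher and 440 lower around a median of -0.06. Leaving out brain-recovered replicate 12 gave 245, and leaving out naive replicate 8 or naive replicate 1 gave 40 or 42. Without naive replicate 9 and without brain-recovered replicate 11 it was 43. Libraries numbered 1 to 6 alone gave 6011, in a comparison of 3 against 3 whose 3 naive libraries were all among the 4 with fewer than 10000 entries above 0. Those numbered 7 to 12 alone gave 0 (181 higher and 825 lower at an unadjusted p below 0.05).

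The smallest p in the set tests belonged to the lists of myeloid progenitor granule genes, immediate early and heat shock genes, and unfolded protein and integrated stress response genes. None of these 3 calls held with an estimated correlation (adjusted p = 0.083, 0.261 and 0.299 with an estimated correlation). All 5 lists that passed lost their call in libraries 1 to 6 alone (adjusted p 0.962 to 0.998) and in the fry test for one direction (0.207 to 0.323). Of the 11 tested myeloid progenitor granule genes, 3 rose over all genes tested and 7 when adjusted over the list alone, and none fell. Elane, the neutrophil elastase of the primary granules (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215), was at 848, 17187 and 65623 in brain-recovered replicates 5, 6 and 10. It was at 4.48 and 12.4 in replicates 4 and 11, listed at 0 in replicate 12, and at 0 to 7.89 in the naive libraries (log2 difference 5.98 ± 1.39 SE, n = 6 per group, limma adjusted p = 0.00835). Mpo, the myeloperoxidase of the same granules (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), had 163 to 7677 in replicates 5, 6, 10 and 11, 14 in replicate 4, 0.231 in replicate 12 and 0.288 to 15.6 in the naive libraries (5.86 ± 1.40, limma adjusted p = 0.0125). Srgn, which encodes the granule proteoglycan serglycin, was at 53.3 to 7281 in 5 brain-recovered libraries, listed at 0 in replicate 12, and at 0 to 12.2 in the naive libraries (6.71 ± 1.37, limma adjusted p = 0.00197). The list passed the set test against all other genes (camera adjusted p = 9.56e-14, median log2 difference 3.62). In libraries 1 to 6 alone it pointed to the opposite direction (0.998). The Elane call was lost without brain-recovered replicate 5, 6 or 10 (limma adjusted p 0.0506, 0.124 and 0.192), with sample weights (0.186), without a filter (0.0813) and in libraries 1 to 6 alone (0.117). The Mpo call was lost without naive replicate 7 or 9 (0.0685 and 0.0569), without brain-recovered replicate 6, 10 or 11 (0.094, 0.0621 and 0.0758), with a filter of at least 10 in 6 libraries (0.0585) and in libraries 1 to 6 alone (0.117).

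Of the 16 tested immediate early and heat shock genes, 2 rose over all genes and 7 when adjusted over the list alone. They were Ier2, an immediate early gene (5.62 ± 1.30 SE, n = 6 per group, limma adjusted p = 0.00835), and Hspa8, the constitutive heat shock cognate chaperone (5.75 ± 1.33, limma adjusted p = 0.00835). Ier2 was listed at 0 in 4 naive libraries and reached 5.64 in naive replicate 9, against 1.36 to 3196 in the brain-recovered libraries. The inducible chaperone gene Hspa1b and the cytosolic chaperone gene Hsp90aa1 missed the threshold over all genes, with differences of 4.76 ± 1.28 and 4.64 ± 1.32 and limma adjusted p of 0.0539 and 0.104. The list passed the set test (camera adjusted p = 1.04e-09, median 2.38; adjusted p = 0.261 with an estimated correlation). Its call was also lost with a filter of at least 10 in 6 libraries (0.0945) and in libraries 1 to 6 alone (0.962). The Ier2 call was lost without naive replicate 8 (0.0507) or brain-recovered replicate 6 or 10 (0.06 and 0.111) and with sample weights (0.213), and that of Hspa8 without naive replicate 8 (0.0616) or brain-recovered replicate 4 or 11 (0.0531 and 0.0751).

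Of the 13 tested genes of the unfolded protein and integrated stress responses, 2 rose over all genes and 3 when adjusted over the list alone. Hspa5, the chaperone BiP of the endoplasmic reticulum (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), was at 248 to 1574 in 5 brain-recovered libraries, 8.55 in replicate 12 and 0 to 20.9 in the naive libraries (6.01 ± 1.43 SE, n = 6 per group, limma adjusted p = 0.0125). Hsp90b1, another chaperone of the endoplasmic reticulum, was at 117 to 925 in the same 5 libraries, 4.12 in replicate 12 and 0 to 13.6 in the naive libraries (5.95 ± 1.38, limma adjusted p = 0.00839). Calr, which encodes the chaperone calreticulin and stood in both this list and the granule list, had a difference of 4.75 ± 1.38 that did not pass over all genes (limma adjusted p = 0.113). The set test gave a camera adjusted p of 5.71e-07 with a median of 2.24, and the call was lost at an adjusted p = 0.299 with an estimated correlation and in libraries 1 to 6 alone (0.962). The Hspa5 call was lost without naive replicate 2 (0.0559) or brain-recovered replicate 4 or 11 (0.0628 and 0.0538), and that of Hsp90b1 without naive replicate 8 (0.0828) or brain-recovered replicate 4 (0.0554).

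Lipid handling and phagocyte genes had 1 of 16 tested members higher over all genes and 5 when adjusted over the list alone. Ctsb, the lysosomal protease cathepsin B, rose by 6.59 ± 1.42 on the log2 scale (SE, n = 6 per group, limma adjusted p = 0.00386). It was at 0.151 to 28.3 in the naive libraries, 32.4 to 11695 in 5 brain-recovered libraries and 0.167 in replicate 12. The lysosomal protease genes Ctsz and Ctsl and the lipid carrier gene Apoe had differences of 3.70 ± 1.28, 3.65 ± 1.32 and 3.51 ± 1.29 with limma adjusted p of 0.32, 0.404 and 0.445 over all genes. The set test gave a camera adjusted p of 0.0282 (median 1.20; adjusted p = 0.991 with an estimated correlation). That call was also lost without naive replicate 7 (0.0628), 8 (0.069) or 9 (0.0925) and without brain-recovered replicate 6 (0.0994) or 10 (0.182). It was lost as well with quantile normalization (0.275), sample weights (0.0916), a filter of at least 10 in 6 libraries (0.0699) and a pseudocount of 0.1 (0.0535), and in libraries 1 to 6 (0.998) or 7 to 12 alone (0.139). It turned to the opposite direction, with an adjusted p of 0.754, in entries of exact gene length only.

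Oligodendrocyte lineage genes, which mark the myelin-forming cells of the brain, passed the set test with 0 of 13 members past the threshold over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.0167, median 1.43; adjusted p = 0.991 with an estimated correlation). Mbp, which encodes myelin basic protein (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637), was at 4239, 5174 and 6044 in brain-recovered replicates 4, 5 and 6. It was at 10.7, 7.16 and 1.6 in replicates 10, 11 and 12, and at 0 to 18.7 in the naive libraries (4.97 ± 1.40 SE, n = 6 per group, limma adjusted p = 0.097). The myelin gene Mobp had 1271, 1854 and 2932 in replicates 4, 5 and 6, 245 in replicate 11, 0.177 and 0.366 in replicates 10 and 12, and 3.58 to 23.2 in the naive libraries (limma adjusted p = 0.602). Mag, a myelin-associated glycoprotein, was at 5803 in replicate 6 and at most 50.7 in every other library (limma adjusted p = 0.443). In libraries 7 to 12 alone the differences of Mbp and Mobp were -1.51 and -0.52. The list call was lost without naive replicate 7 (0.0628) or brain-recovered replicate 6 (0.182), with quantile normalization (0.312) and in libraries 1 to 6 (0.998) or 7 to 12 alone (0.666). It was also lost in entries of exact gene length only (0.379), and Mbp, Mobp and Mag kept their labels because no rule excluded them and not by their own length.

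The other 26 lists tested did not pass, with camera adjusted p from 0.0934 for the oxidative stress defence genes to 0.982. In 25 of them no member passed over all genes, and in the resolution and annexin list Anxa5, a phospholipid-binding protein, rose by 5.57 ± 1.34 on the log2 scale (SE, n = 6 per group, limma adjusted p = 0.0134). It was at 558 to 4329 in brain-recovered replicates 4, 5 and 11, at 16.7 and 12.3 in replicates 6 and 10, at 0.471 in replicate 12 and at 0 to 9.58 in the naive libraries. The Anxa5 call was lost without naive replicate 1 or 7 (0.0615 and 0.0514) and without brain-recovered replicate 4, 5 or 11 (0.140, 0.245 and 0.0858). Of 15 oxidative stress defence genes, 3 passed when adjusted over the list alone, namely Sod1, a superoxide dismutase (3.95 ± 1.24), Ftl1, the light chain of the iron store ferritin (4.03 ± 1.39), and Gpx1, a glutathione peroxidase (4.03 ± 1.40). Of 10 inflammatory cytokine and chemokine genes 2 passed when adjusted over the list alone, the chemokine gene Ccl4 (3.81 ± 1.27) and the growth factor gene Tgfb1 (3.15 ± 1.22). Il1b, which encodes interleukin 1 beta, had 762 and 3709 in brain-recovered replicates 6 and 10 and at most 23.8 elsewhere. A single member passed when adjusted over the list alone in each of the lists of maturing neutrophils (Lcn2, lipocalin 2), antigen presentation (Cd74, the invariant chain), astrocytes (Clu, clusterin), endothelium (Ly6c1), growth factors (Spp1, osteopontin), complement (Cfp, properdin), iron handling (Ftl1) and annexins (Anxa5).

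No member passed, even when adjusted over the list alone, among 20 haematopoietic stem and progenitor markers (median log2 difference 0.69), 10 erythroid, 6 megakaryocyte, 14 monocyte and macrophage, 8 microglia, 10 B lineage, 8 T and NK cell, 7 mast cell, 10 neuron and 5 choroid plexus genes. The same held for 19 cell cycle, 18 interferon response, 14 hypoxia and glycolysis, 17 adhesion and homing, 14 apoptosis and survival, and 7 zinc handling genes, and for the 2 tested sex chromosome genes, which were too few for a set test. Ly6a, which encodes the stem cell antigen Sca-1, was at 35095 in brain-recovered replicate 6 and at most 37.9 in every other library (3.31 ± 1.32, limma adjusted p = 0.553). In the same list Gfi1 was at 2451 in brain-recovered replicate 10 and at most 31.5 elsewhere. Procr was at 0 to 14.0 in the naive and 0 to 22.0 in the brain-recovered libraries, where median values above 0 were 10.8 to 12.6. For genes at such low values, the lack of a call does not show that they were unchanged. The proliferation marker gene Mki67 was at 2749 and the glycolytic enzyme gene Pkm at 2064 in brain-recovered replicate 10, and the interferon-induced gene Isg15 at 2548 and Pkm at 485 in replicate 6. The limma adjusted p was 0.812 for Mki67, 0.633 for Pkm and 0.584 for Isg15. For zinc handling, B lineage, T and NK cell, choroid plexus and interferon genes the median difference was positive (0.79, 0.35, 0.84, 0.13 and 0.41) while the set test, which compares a list with all other entries, pointed lower.

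The labels Mt1 and Mt2, for the metallothioneins that the title of the series concerns, stood on entries with large differences, but the values do not have the lengths of those genes. The entry labelled Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327 in GRCm38) had 3374 ± 2905 in naive and 346948 ± 395005 in brain-recovered cells (SD, n = 6 each), a log2 difference of 5.60 ± 1.35 (SE, limma adjusted p = 0.0134; exact permutation p = 0.0108). The entry labelled Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) had 769 ± 687 and 107439 ± 129104 (SD, n = 6 each), a difference of 6.36 ± 1.43 (SE, limma adjusted p = 0.00559; exact permutation p = 0.00649). In both, 5 of the 6 brain-recovered libraries exceeded every naive library, and replicate 12, at 1249 and 1167, lay within the naive range. With 1 library left out, the limma call of the entry labelled Mt1 held only without brain-recovered replicate 12, with an adjusted p of 0.0585 to 0.204 in the other 11 fits. That of the entry labelled Mt2 was lost without naive replicate 3 (0.0634). Neither entry passed limma after quantile normalization (differences of 2.28 and 2.88) or library totals (3.59 and 4.36), where exact permutation p was 0.0281 and 0.00216, and 0.0173 and 0.00216. Neither passed without the libraries under 10000 entries (limma adjusted p 0.803 and 0.798) or in libraries 7 to 12 alone (0.820 for both). The entry labelled Mt1 also lost its call with upper quartile scaling (0.0949) and without a filter (0.369). The authors' deposited table lists fold changes of 103 and 140 with P of 0.059 and 0.0705 for these entries. The values of the entry labelled Mt1 are whole reads per 681 bases in 11 of 12 libraries, and in at most 2 of 12 at the annotated lengths of Mt1 or its transcripts (549, 633, 1085 and 1246 bases). Those of the entry labelled Mt2 are whole reads per 204 bases in 12 of 12, and in 1 of 12 at 388, 511 or 588 bases (tolerance 0.05 of a read). No value is therefore given here for Mt1 or Mt2 as genes. Slc30a1, the zinc exporter and the member of the zinc handling list with the smallest p, had 0 to 34.1 in the naive and 0 to 65.6 in the brain-recovered libraries (limma adjusted p = 0.954).

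Summed values of cell type markers differed widely between single brain-recovered libraries. The myeloid progenitor granule sum was 95.8 ± 71.0 in naive and 29382 ± 46646 in brain-recovered cells (SD, n = 6 each), with all 6 brain-recovered libraries above every naive library. The separation was narrow, at 183 in brain-recovered replicate 12 against 181 in naive replicate 1. In that replicate 12 the list members Ctsg and Igfbp4 were at 122 and 51.7, with Elane listed at 0 and Mpo at 0.231. The log2 difference was 6.52 (exact permutation p = 0.00216, the smallest the 924 assignments allow, adjusted p = 0.0346 over 16 lists). It was the only one of the 16 cell type sums to pass. Leaving out any 1 naive library gave an adjusted p of 0.0693, although all 6 brain-recovered libraries stayed above every naive one, since 2 of 462 assignments were then as extreme in place of 2 of 924. The median of log2 values in place of the sum gave 0.364. The sums of stem and progenitor markers (166 ± 72.6 in naive and 6756 ± 14025 in brain-recovered cells, SD) and of erythroid genes (80.1 ± 47.8 and 3110 ± 5870) had exact permutation p of 0.0152 and 0.0108, and adjusted p of 0.0606 and 0.0577. Those of neuron genes (102 ± 37.7 and 390 ± 263) and oligodendrocyte genes (110 ± 60.8 and 7264 ± 11254) had exact permutation p of 0.00866 and 0.0411, and adjusted p of 0.0577 and 0.132. Without brain-recovered replicate 12, 8 of the 16 sums passed; without replicate 4, 3 passed, without replicate 10, 2, and without replicate 11, 3, again with 462 assignments in place of 924.

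The monocyte and macrophage sum was 99045 in brain-recovered replicate 10. There the protease gene Ctss was at 66620, the complement gene C1qa at 19416 and the integrin gene Itgam, which encodes CD11b, at 10707. The sum was between 1.94 and 4331 in the other 5 brain-recovered libraries (exact permutation p = 0.165, n = 6 per group). The microglia sum was 10031 and 8035 in brain-recovered replicates 6 and 10 and 0.838 to 548 in the others (exact permutation p = 0.284). The T and NK cell sum was 26376 in brain-recovered replicate 6, of which the T cell receptor gene Trac gave 26281, and at most 192 in every other library (exact permutation p = 0.656). The endothelial and mural sum was 34589 in replicate 6 (exact permutation p = 0.351), the antigen presentation sum 13595 in replicate 6 (p = 0.411), the astrocyte sum 1215, 1245 and 3450 in replicates 4, 5 and 6 (p = 0.0519) and the mast cell sum 1637 in replicate 11 (p = 0.0801). The megakaryocyte sum was 10345 in naive replicate 1, where the platelet factor gene Pf4 was at 6590, and 17.2 to 144 in the other naive libraries (exact permutation p = 0.439). The neutrophil sum was 13043 and 4854 in naive replicates 1 and 3 and 17700 in brain-recovered replicate 4 (exact permutation p = 0.903), and the B lineage and choroid plexus sums had exact permutation p of 0.766 and 0.186. All of these sums had adjusted p above 0.05.

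**Figure D2:**
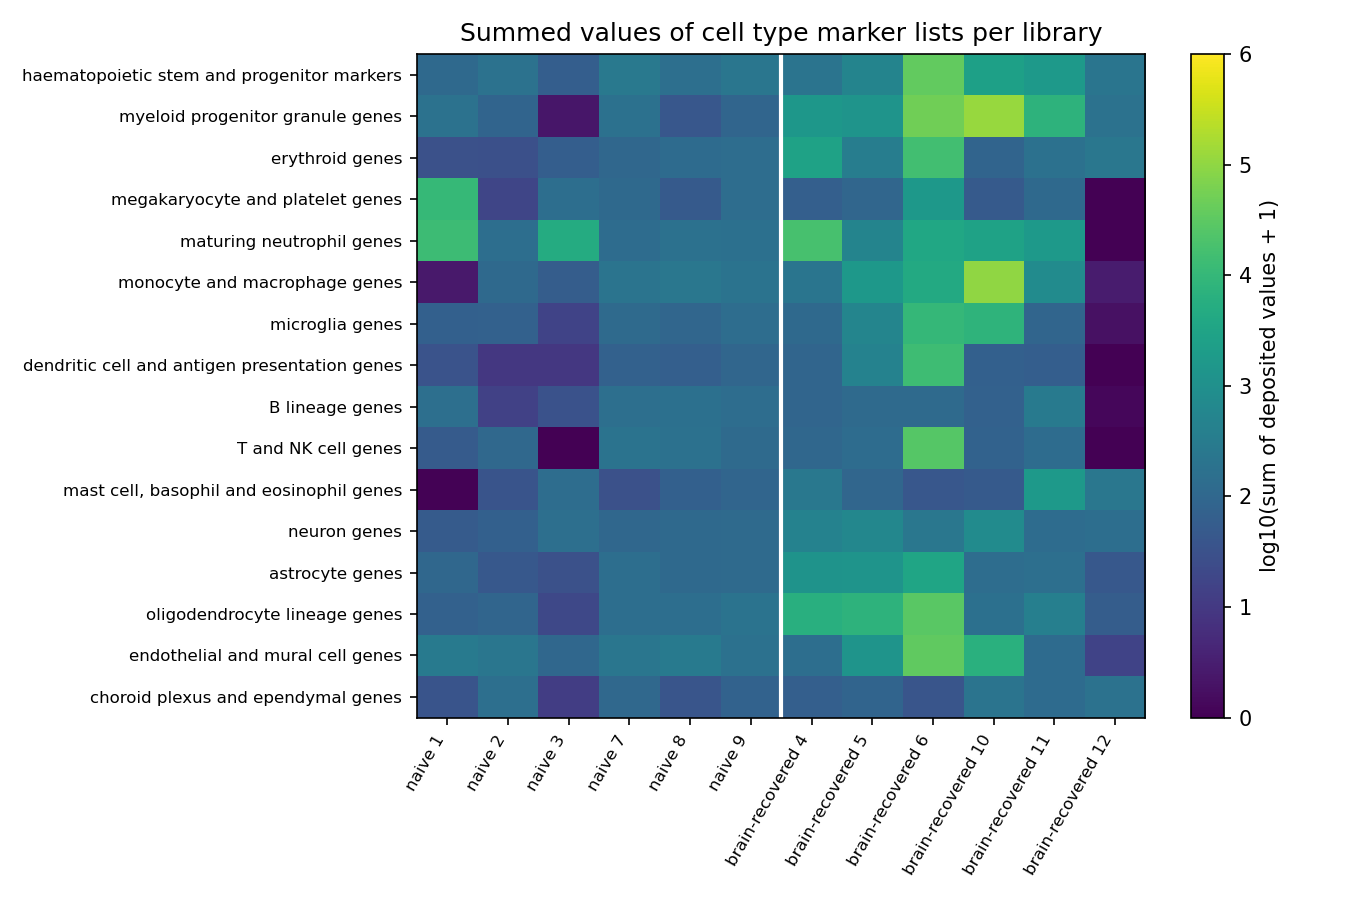
Sum of deposited values over each of 16 lists of cell type markers (vertical axis) in each of the 12 libraries (horizontal axis), with colour giving log10(sum + 1). The myeloid progenitor granule sum reaches 116440 in brain-recovered replicate 10, and the monocyte and macrophage sum reaches 99045 in the same library.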

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

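Of the tests of explanations in this part, the difference without sparse libraries, libraries 1 to 6 or 7 to 12 alone and the olfactory ratio over all entries were chosen after the result was seen, and what the splits and the planned term for the number range would show was written down only once their counts had been seen.

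In 14 of 74 groups of 6 libraries examined, a single library stood apart by Dixon's ratio of its gap to the whole range, where chance gives about 1 in 20. Among naive libraries, replicate 3 was far above the others for Rpl8 (ratio 0.764; log2 value 5.71 against 1.35 for the next), replicate 9 for Cst3 (0.713; 4.10 against 1.64) and for Ier2 (0.797; 2.73 against 0.55), and replicate 1 for Tmsb4x (0.692; 11.67 against 4.49) and for the megakaryocyte sum (0.673; 13.34 against 7.18). Naive replicate 3 was far below the others for the sums of myeloid progenitor granule genes (0.670; 1.21 against 5.43), microglia genes (0.692; 4.00 against 6.15) and T and NK cell genes (0.758; 0 against 5.76). Naive replicate 1 was lowest for the sums of monocyte and macrophage genes (0.685; 1.36 against 5.85) and mast cell genes (0.690; 0.15 against 4.94). Brain-recovered replicate 12 was far below the others of its group for Hspa5 (0.639; 3.26 against 7.96), the entry labelled Mt1 (0.677; 10.29 against 16.88), the maturing neutrophil sum (0.635; 0 against 8.96) and the B lineage sum (0.744; 0.31 against 6.18).

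The 65 entries that were higher in brain-recovered cells were set against 4 technical accounts. Read depth was not among them and stays open as a source. The mean log2 number of reads was higher by 1.76 in the brain-recovered group (exact permutation p = 0.0173), and the library constant is not the total of the reads. With scaling to library totals 0 calls were left, and unadjusted p below 0.05 (limma) gave 163 higher and 456 lower. Chance was not excluded, since the bound of fewer than 5 in 100 splits was written down once their counts had been seen. Of 100 splits of the 12 libraries, the real one included, 3 gave at least 65 calls, and the other 2 gave more (760 and 145). The highest set naive replicates 1, 2, 3, 7 and 8 and brain-recovered replicate 12 against the rest, which points to a structure of the samples. Sparse libraries could not be judged as the whole source. The median difference of the 65 was 6.54 without the libraries under 10000 entries (5.95 with them), but the 65 had been selected on these same data. Over all entries tested in that setting the median was -0.06. Unadjusted p below 0.05 (limma) gave 481 higher and 440 lower, and 3 calls were left among 8 libraries. The number range cannot be told apart by a term for it, which kept 65 calls, because each range holds as many libraries of both groups and the term cannot move the difference. Libraries 1 to 6 alone gave 6011 calls and libraries 7 to 12 alone 0. What stays open is that part of the reads in naive libraries may be spread evenly over genes, as reads from DNA would be. With the most abundant 1% of the entries above 0 left out, olfactory receptor genes, which marrow is not known to use, had a mean value 1.06 times that of other protein-coding genes (median over naive libraries, range 0.730 to 1.46). That met the prediction for even coverage, which had been written down before this ratio was seen. Over all entries, a ratio chosen afterwards, it was 0.331 times (0.0717 to 0.431). The 2 ratios do not show how much of the group difference even coverage would explain. In brain-recovered replicates 4, 5, 6, 10, 11 and 12 the first ratio was 0.979, 0.744, 0.140, 0.0858, 1.21 and 1.11 (exact permutation p = 0.190 for the group difference, n = 6 per group) and the second 0.0480, 0.0571, 0.0245, 0.01995, 0.101 and 0.170 (p = 0.0238). A change in the cells after injection stays open as well and was not tested apart from it.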

How the results depend on the processing

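The variance prior without a trend, the omission of sparse libraries, libraries 1 to 6 or 7 to 12 alone, exact-length entries and labels as deposited were chosen after seeing the data. No paired analysis was possible because the groups share no replicate number. The 65 calls became 0 under quantile normalization and under library totals, 33 with a filter of at least 10 in 6 libraries, 115 with a variance prior without a trend, 3 without the libraries under 10000 entries, 6011 in libraries 1 to 6 alone, 0 in libraries 7 to 12 alone, and 40 to 245 with 1 library left out; 7 other alternatives gave 49 to 65. In each of these settings all of the 65 that were tested stayed higher in brain-recovered cells. Having been selected for large differences in the same libraries, they could hardly change direction, so this is no independent check. The 5 lists became 0 with an estimated correlation, 0 with fry for one direction (smallest adjusted p 0.207) or mixed (0.131), 3 in entries of exact length, 8 with labels as deposited, 3 under quantile normalization, 0 in libraries 1 to 6, 3 in libraries 7 to 12, and 3 to 8 with 1 library left out. The 1 cell type sum became 0 with the median of log2 values and 0 to 8 with 1 library left out. The entries labelled Mt1 and Mt2 stayed higher with exact permutation p of 0.00216 to 0.0281, at 4.96 to 6.91 and 5.75 to 7.40 with 1 library left out and 2.28 and 2.88 under quantile normalization, but their limma calls held in 1 and 11 of the 12 fits with 1 library left out. Of the 47 named calls, 15 held in every such fit.

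The set test of metallothioneins and zinc handling pointed lower (adjusted p 0.982) and turned higher with labels as deposited (0.00017), where the entries labelled Mt1 and Mt2 enter the list, and with quantile normalization (0.837), sample weights (0.903), no filter (0.920), the stricter filter (0.991), without sparse libraries (0.877), in libraries 1 to 6 (0.998) and without naive replicate 2 or 7 or brain-recovered replicate 6, 10 or 12 (0.881 to 0.989; 0.768 to 0.989 over all 12 omissions). It was also higher with fry (0.479), which asks whether the list moves at all and not whether it differs from other entries. Myeloid granule genes turned in libraries 1 to 6 (0.998; 1.39e-16 to 1.12e-07 with 1 library left out) and lipid handling genes in exact-length entries (0.754). Of log2 sums, megakaryocyte and B lineage genes turned with the median of log2 values (0.30 and 0.25), choroid plexus genes without their most abundant member (-0.41), and with 1 library left out maturing neutrophil genes ran from -0.56 to 2.26, T and NK cell genes from -0.34 to 2.60 and B lineage genes from -0.98 to 0.62. In libraries 7 to 12 alone Slc30a1 (-0.91), Ly6a (-0.46), Apoe (-1.39), Cd74 (-0.13), Slc1a2 (-0.56), Mbp (-1.51), Mobp (-0.52), Isg15 (-1.25) and Mcl1 (-0.94) were lower. Fewer samples entered the settings that leave libraries out; for the others the cause was not tested. Reads alone did not order the entries above 0, since naive replicates 1 and 8 had 1258794 and 1398024 reads with 7164 and 16269 entries.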

Other observations

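All tests of explanations in this part were chosen after the results they bear on had been seen, as was the count of ribosomal protein genes.

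Ribosomal protein genes were counted because several had been seen among the largest differences, so the count describes the calls and tests nothing. Of 30 tested genes of the small and large ribosomal subunits with a usable name, 29 had a higher mean log2 value in brain-recovered cells, with a median difference of 3.19, and 10 passed the threshold (33.3%, against 0.233% of the other named genes). Among them were Rpl23, Rpl8, Rplp2, Rps10, Rps14, Rps15, Rps4x, Rps9 and Rpsa, with differences from 5.33 ± 1.31 for Rps15 to 7.96 ± 1.41 for Rpl23 (SE, n = 6 per group, limma). With 1 library left out, 4 of the 10 calls held in every fit, and 5 held without brain-recovered replicate 11, 6 without brain-recovered replicate 6, naive replicate 1 or naive replicate 9, and 7 to 10 without each of the others. None of the 10 held under quantile normalization or in libraries 7 to 12 alone, none of the 9 that could be tested held under library totals, and 1 of 10 held without the libraries under 10000 entries.

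Some list members that did not pass stood above every naive library in 1 or more brain-recovered libraries. The megakaryocyte gene Treml1 was above every naive library in 5 of 6 brain-recovered libraries at 5.05 to 35.0 (limma adjusted p = 0.852). These are low values, and those in replicates 4 and 5 (6.60 and 5.05) lay below the median value above 0 of the library (11.2 and 10.9). Gfi1b, a transcription factor of erythroid and megakaryocytic cells, was at 133 in brain-recovered replicate 12 and 1.09 to 28.3 in the others (limma adjusted p = 0.553). Mcl1, a survival gene of the Bcl2 family, was at 757 in replicate 5 and listed at 0 in replicates 10 and 12 (adjusted p = 0.404). The glutamate transporter gene Slc1a2 was at 2096 in replicate 6 and 31.2 to 182 in replicates 4, 5, 10 and 11, against at most 21.0 in the naive libraries (adjusted p = 0.553), and the neuronal gene Nrgn at 311 in replicate 10 and 114 in replicate 12, against at most 32.6 in the naive libraries (adjusted p = 0.927).

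The entries labelled Mt1 and Mt2 raise the hypothesis that labels and values are displaced against each other in that stretch of the table. Read in alphabetical order of labels, the 13 entries from the one labelled Mt1 on gave the exact lengths of 11 of the 13 mitochondrially encoded protein genes, in their alphabetical order, from 681 bases for mt-Atp6 and 204 for mt-Atp8 to 1824 for mt-Nd5 and 519 for mt-Nd6. Counted place by place the number was 7, because an entry without a symbol is missing from that order, and the count was changed to matches in order on seeing this (at most 1 from 1000 random starting entries). The tables argue against these entries holding metallothionein reads, since 0 of the 2 gave whole reads in at least 10 of 12 libraries at any annotated length of the labelled gene, a bound lowered from 12 once 681 bases was seen to give 11, and mitochondrial transcripts are a candidate source of their difference. Entries with these 11 lengths held 0.370% to 3.06% of reads in naive libraries and 14.9%, 16.2%, 20.4%, 14.9%, 13.5% and 1.46% in brain-recovered replicates 4, 5, 6, 10, 11 and 12.

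Which entry holds the reads of Mt1 was not settled. Further on, the entries labelled Mthfs and Mthfsd have the exact lengths of Mta2 and Mta3 (4093 and 5319 bases), and entries shortly before them, labelled Mthfd1l, Mthfd2 and Mthfd2l, have 540, 556 and 538 bases, which match no gene within 40 places. The entry labelled Mthfd1l held 3057, 483, 61, 0, 5 and 15 reads in brain-recovered replicates 4, 5, 6, 10, 11 and 12 and 1, 0, 0, 21, 0 and 13 in naive replicates 1, 2, 3, 7, 8 and 9.

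The higher oligodendrocyte values in brain-recovered replicates 4, 5 and 6 could come from RNA of host brain cells carried along, a hypothesis on which the test stayed undecided. In it, 1 brain-recovered library held all 4 of the most abundant members of the list, Mbp and Mobp among them, above every naive library, with 3, 3, 4, 0, 1 and 0 of them in replicates 4, 5, 6, 10, 11 and 12. The tables argue against evenly spread reads as the source, since the list mean was more than 10 times the library's median value above 0 in 3 brain-recovered libraries (39.7, 49.1 and 176 in replicates 4, 5 and 6). No sort after recovery from the brain is named in the labels used here, so expression in the recovered cells and carried-over RNA cannot be told apart for these genes.

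For the gene lists, chance could not be excluded, as 12 of 100 splits of the libraries gave at least 5 lists past the threshold, and the highest other split gave 7.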
